A study of Oryza sativa with 4 samples.

How the data were processed

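Total RNA of roots from 14-day-old rice seedlings treated with 100 µM ABA for 4 hours was extracted with TRIzol, labelled with biotin and hybridised to the Affymetrix GeneChip Rice Genome array, per the labels' protocols. The 4 arrays fall into 2 groups, 2 of the wild type and 2 of the Osabl1 knockout mutant, and the labels call the arrays of a group biological replicates. One of the mutant labels writes the locus with a digit missing, and both were taken as the same mutant. The deposited table holds 1 linear intensity per probe set and array, which is never negative. MAS5 is named in the submitters' processing notes without a role or version. Neither the scaling target nor detection calls are given in the sources used here. The array medians of the deposited intensities were 11.85 and 13.16 in the wild type and 11.18 and 12.86 in the mutant, so the arrays do not share a common median. No scan date or batch is given in the sources used here.

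The table has 57381 probe sets, of which 64 are reporter probe sets and a further group are AFFX controls. Among the other 57194, the platform annotation pairs 22436 with 1 gene, 95 with several and 34663 with none, and no gene is named from a probe set with several. All 22436 were found in the reference gene table (used for names and chromosomes), where 2452 genes carry a name beyond a LOC number. The tables give no gene descriptions, so lists written as word patterns could only match gene names, and 25 of the 38 lists had under 5 tested genes and were not tested. The ABA loci were matched by name after some values had been seen, and 22 of the 31 matched.

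Values were analysed as log2(intensity + 16) with no further scaling. Probe sets other than controls were tested if their mean over the 4 arrays was above the median. The fit was limma lmFit and eBayes with a trend (limma 3.58.1, R 4.3.3), mutant minus wild type, with Benjamini-Hochberg adjustment at 0.05 over the tested probe sets. Reporter and AFFX probe sets were fitted and adjusted together with the tested probe sets, and they stay out of the counts and lists. Gene lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01 on the brightest probe set of each gene, with camera at an estimated correlation and fry beside it. Figures were drawn with matplotlib 3.10.9 from tables made with R and pandas 2.3.3. Standard errors are those of limma after moderation, and SDs are of the deposited intensities.

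The tests, the lists, the ABA loci, the rule for named genes and the first set of alternatives were fixed before the data were examined. Genes were named in this order: OsABL1 first, then up to 15 per direction among those past the threshold with the mutant arrays on 1 side of the wild-type arrays. Where fewer than 5 passed, the rule took the 10 with the smallest p among genes at least 2-fold apart in all 4 array pairs. It also took up to 4 members per list with the smallest p and each matched ABA gene. Only probe sets with exactly 1 gene were eligible, so the called probe sets without a gene were named after their values were seen. Fewer than 10 genes qualified among the lower ones.

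On simulated data with 200 changed probe sets among 28597, the fit recovered 8.96% at 2-fold, 95.5% at 4-fold and 100% at 8-fold. It made 6 calls among the unchanged probe sets, and 0 calls when nothing was changed. The simulated noise was independent for each probe set and array, with variances drawn from the fit to these arrays. It held no brightness shift shared by the probe sets of an array. The first set of alternatives was quantile normalization, centring each array on its median, pseudocounts of 1 and 64, no filter, the top 30% by mean, other variance models, the replicate number as a block, leaving out each array, other list tests and least squares without moderation. Added after the data had been seen were centring together with the block, centring together with leaving out each array, and 36 gene family lists built from gene names. A table of the probe sets with the smallest p had been seen before the family lists were built, and it held members of the HAK, ABCG, jasmonate synthesis, glutaredoxin and CASP-like families, so these 5 lists are not independent evidence of their direction.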

Results

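Gene expression was measured in the roots of 14-day-old rice seedlings (Oryza sativa, japonica cultivar Zhonghua 11) that had been treated with 100 µM abscisic acid (ABA, the hormone that rises in plants under drought and salt stress) for 4 hours. Roots of a knockout mutant of OsABL1, a basic leucine zipper (bZIP) transcription factor gene, were set against roots of the wild type, with 2 biological replicates of each genotype and 1 Affymetrix GeneChip Rice Genome array per replicate. All 4 arrays come from ABA-treated roots, so the comparison asks how the transcripts of the mutant and the wild type differ after ABA, and a response to ABA itself was not measured. The values are the deposited intensities (MAS5 is the tool named by the submitters), and 28597 probe sets with a mean log2 value above the median of all probe set means entered the test. The replicate 2 array was brighter than the replicate 1 array in both genotypes, by a median log2 difference of 0.25 in the wild type and 0.21 in the mutant. The median difference between the genotypes was 0.01. Across the tested probe sets, Pearson's r was 0.9745 between the wild-type replicates, 0.9747 between the mutant replicates, and from 0.968 to 0.977 between arrays of different genotypes; these are correlations across probe sets, which are not independent replicates. The number of arrays limits the precision of every value.

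The knockout was to be checked first at OsABL1 itself. No probe set is paired with the labelled locus or the gene's name in the annotation used here, so no value is given for the targeted gene, and its loss was not checked at the transcript level. The array also carries 64 probe sets for reporter and marker sequences that are not rice genes, and 2 of these passed the threshold. The first was at 2.5 ± 2.3 in the wild type and 2387 ± 168.7 in the mutant (intensity, mean ± SD, n = 2 each), a log2 difference of 7.03 ± 0.31 (SE; limma, adjusted p = 5.529e-08). The second was at 17.3 ± 2.6 in the wild type and 232.0 ± 6.7 in the mutant (SD, n = 2 each), a log2 difference of 2.90 ± 0.30 (SE; limma, adjusted p = 0.0007431), but it missed the threshold when dim probe sets were also tested (adjusted p = 0.2164). Another, at 5.1 against 56.4 and also higher on both mutant arrays, missed the threshold (limma, adjusted p = 0.05044). The annotation used here does not describe the sequences behind these reporter probe sets. Their identifiers carry sequence codes, which were not looked up here. None of the AFFX control probe sets passed (limma, smallest adjusted p = 1).

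In the mutant, 7 probe sets were higher than in the wild type and 0 were lower (limma, adjusted p under 0.05). At an unadjusted p under 0.05, limma gave 1106 in all, 627 of them lower. This is 3.87% of the tested probe sets, where 5% is expected if nothing differs. The split of the 4 arrays by replicate number gave 4204 (14.7%). On centred arrays the genotypes gave 1562 (5.46%) and the replicate numbers 2039 (7.13%). Least squares without moderation called 0 in either direction after adjustment. Both mutant arrays lay above both wild-type arrays for each of the 7. Of these, 3 are paired with a gene. GRXS3 (LOC4327691, chromosome 1), a glutaredoxin, which is a small thiol oxidoreductase, rose from 58.1 ± 12.9 to 449.6 ± 88.9 (intensity, SD, n = 2 each), a log2 difference of 2.65 ± 0.32 (SE; limma, adjusted p = 0.005126). LOC4340325 (chromosome 6) rose from 5.0 ± 2.8 to 206.4 ± 15, a log2 difference of 3.41 ± 0.29 (limma, adjusted p = 0.0001002). Its second probe set was at 44.1 and 45.2, a log2 difference of 0.03, so the 2 probe sets of this gene disagree. LOC4336614 (chromosome 4) rose from 293.1 ± 165.3 to 1504 ± 102.4, a log2 difference of 2.41 ± 0.37 (limma, adjusted p = 0.04449). The called probe set with the smallest p, which has no gene in the annotation, rose from 18.8 ± 3.5 to 2467 ± 330.2 (SD, n = 2 each), a log2 difference of 6.15 ± 0.31 (limma, adjusted p = 2.225e-07). The other 3 without a gene, identified in the plot of the called probe sets, had log2 differences of 3.68, 2.46 and 2.21. All log2 differences are on the log2(intensity + 16) scale, which understates the change of dim probe sets. With each array centred on its median, or with quantile normalization, 3 of the 7 calls were made, LOC4340325 and the 2 probe sets without a gene that had the smallest p. The fold changes moved little: the log2 difference of GRXS3 was 2.66 ± 0.30 on centred arrays, with an adjusted p of 0.1012 (from 9.609e-09 to 0.7205 over its alternatives), and the prior degrees of freedom of the limma fit went from 12.28 to 6.39. With 1 array left out, the brightness of the groups is no longer balanced. The counts as deposited were then 54 higher and 260 lower without wild-type replicate 1, and 58 and 6 without wild-type replicate 2. They were 33 and 39 without mutant replicate 1, and 39 and 131 without mutant replicate 2, with all 7 among the calls each time.

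**Figure D1:**
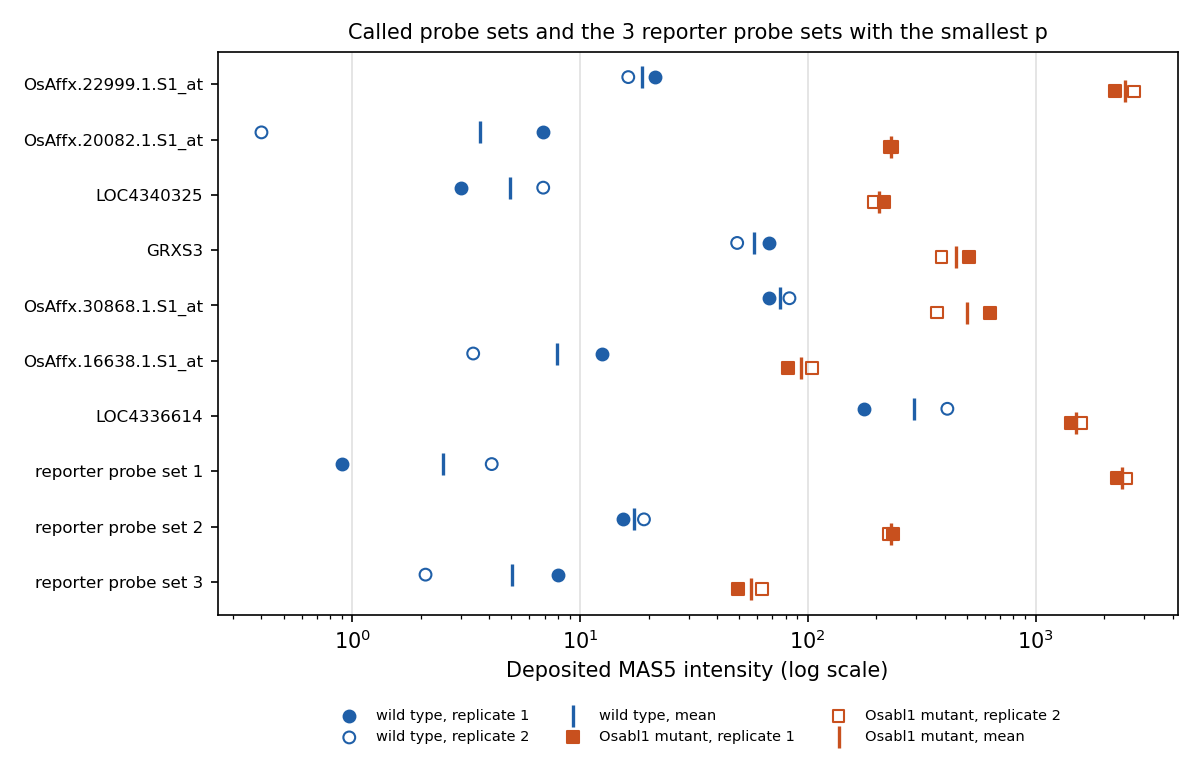
Deposited intensity (horizontal log axis) of the 7 called probe sets and the 3 reporter probe sets with the smallest p; blue circles are wild-type arrays, orange squares mutant arrays, filled for replicate 1 and open for replicate 2, and vertical ticks mark the mean of 2 arrays. Both mutant arrays lie above both wild-type arrays in every row, with reporter probe set 1 at 2267 and 2506 in the mutant and at 0.9 and 4.1 in the wild type.

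Counted by size alone, 20 probe sets were at least 2-fold higher and 9 at least 2-fold lower in all 4 pairs of a mutant and a wild-type array. Without wild-type replicate 1 these counts were 83 and 339, without wild-type replicate 2 they were 169 and 30, without mutant replicate 1 they were 115 and 58, and without mutant replicate 2 they were 67 and 161. The arrays of the genotypes did not overlap for 26.2% of the tested probe sets, where chance gives 33.3% if all 4 arrays are interchangeable. As deposited they are not, since replicate 2 was brighter in both genotypes. Among the genes with the smallest p of these, none beyond the 3 called genes passed the test, so they are given as values. Higher in the mutant were LOC4345030 (398.9 against 1332, log2 difference 1.70), CASPL5B2 (LOC4338988, a CASP-like membrane protein, 48.7 against 188.0, log2 difference 1.66), LOC4326148 (1.62), LOC4334521 (1.71), LOC4343352 (1.43), LOC4349327 (1.39) and LOC4349217 (1.33), with adjusted p from 0.1348 to 0.5437 (limma). The second probe set of LOC4349327 gave 1.29, and that of CASPL5B2 gave 0.28. Lower were HAK16 (LOC4333298), a potassium transporter of the HAK family, at 266.1 in the wild type and 55.5 in the mutant (log2 difference -1.89, limma adjusted p = 0.2069), LOC4349647 (-1.64), LOC4332658 (-1.37) and LOC4340413 (-1.23). LOC4325764 had the largest fall in size, -2.87, but its wild-type arrays stood at 185.7 and 1194 (limma, adjusted p = 0.3006). The second probe sets of LOC4349647 and LOC4340413 gave -0.45 and -0.47. The same count over the 4 arrays split by replicate number was 46 in both directions together, against 29 for the genotypes, and 7 for the crossed split; on centred arrays the counts were 34, 38 and 7.

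Genes of the ABA response were then compared. Of 31 fixed loci, 22 could be matched by name, and all 22 were tested; the other 9, OsABL1 among them, were not analysed here. None differed between the mutant and the wild type over all genes or adjusted over the list alone (limma, smallest unadjusted p = 0.1451, smallest adjusted p over the list alone 0.9659). The median log2 difference was -0.03, with 10 members higher and 12 lower. It depended on single arrays as deposited, at -0.27 without wild-type replicate 1, 0.15 without wild-type replicate 2, 0.05 without mutant replicate 1 and -0.07 without mutant replicate 2, with 0 members passing each time. On centred arrays it lay between -0.10 and 0.07 with 1 array left out. In the fit of all 4 arrays, the 95% intervals of 20 of the 22 lay within 1 log2 unit on either side of 0. The LEA and dehydrin genes, whose products protect cells under dehydration, were bright in both genotypes. RAB21 was at 9855 ± 916.2 in the wild type and 9717 ± 145.6 in the mutant (SD, n = 2 each; log2 difference -0.02, 95% interval -0.52 to 0.48), and LEA3-1 was at 5731 and 5784 (0.02, interval -0.52 to 0.57). RAB16B, RAB16C, RAB16D and LIP9 differed by 0.02, -0.04, 0.09 and -0.11. The signs of LEA3-1, RAB16B, RAB16D and the bZIP factor BZIP23 turned with quantile normalization. The highest intensities on the 4 arrays lay between 12442 and 12803, so these signals stood in the upper part of the recorded range. The largest difference was that of rab25, at 744.7 ± 383.2 and 472.8 ± 212.8, a log2 difference of -0.61 with an interval from -1.46 to 0.24.

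The clade A PP2C phosphatases, which restrain ABA signalling, also showed no called member: PP2C30, PP2C68, PP2C51, PP2C53, PP2C06, PP2C09 and PP2C08 differed by between -0.24 and 0.13. The ABA 8'-hydroxylase genes ABA8OX1 and ABA8OX2, which break ABA down, differed by -0.04 and 0.09. The related bZIP factor BZIP23 was at 2081 in the wild type and 2189 in the mutant (log2 difference 0.06, 95% interval -0.54 to 0.66), and TRAB1 differed by 0.08. The stress NAC factors SNAC2 and NAC5 differed by -0.04 and -0.08, and SALT differed by 0.19. As lists, LEA and dehydrin (8 tested genes), clade A PP2C (7), and ABA receptors and SnRK2 kinases (11) gave adjusted p of 0.5872, 0.5744 and 0.5872 (camera). The LEA and dehydrin list was called lower without wild-type replicate 1 as deposited (mean log2 difference -0.36 against -0.06, adjusted p = 0.01573), but not on centred arrays without that array (-0.20, adjusted p = 0.1333). Over all its alternatives the adjusted p ranged from 0.01573 to 0.95. In simulated data adjusted over all 28597 tested probe sets, a change of 2-fold was recovered for 8.96% of probe sets and one of 4-fold for 95.5%. In that simulation, differences of 2-fold or less were thus mostly not detectable over all genes with 2 arrays per genotype. The simulated noise lacked the brightness shift between replicates seen in the real arrays, so recovery there can differ. Detection in the ABA genes adjusted alone, or in lists of this kind, was not simulated. For single ABA genes the 95% intervals give the sizes that remain possible.

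**Figure D2:**
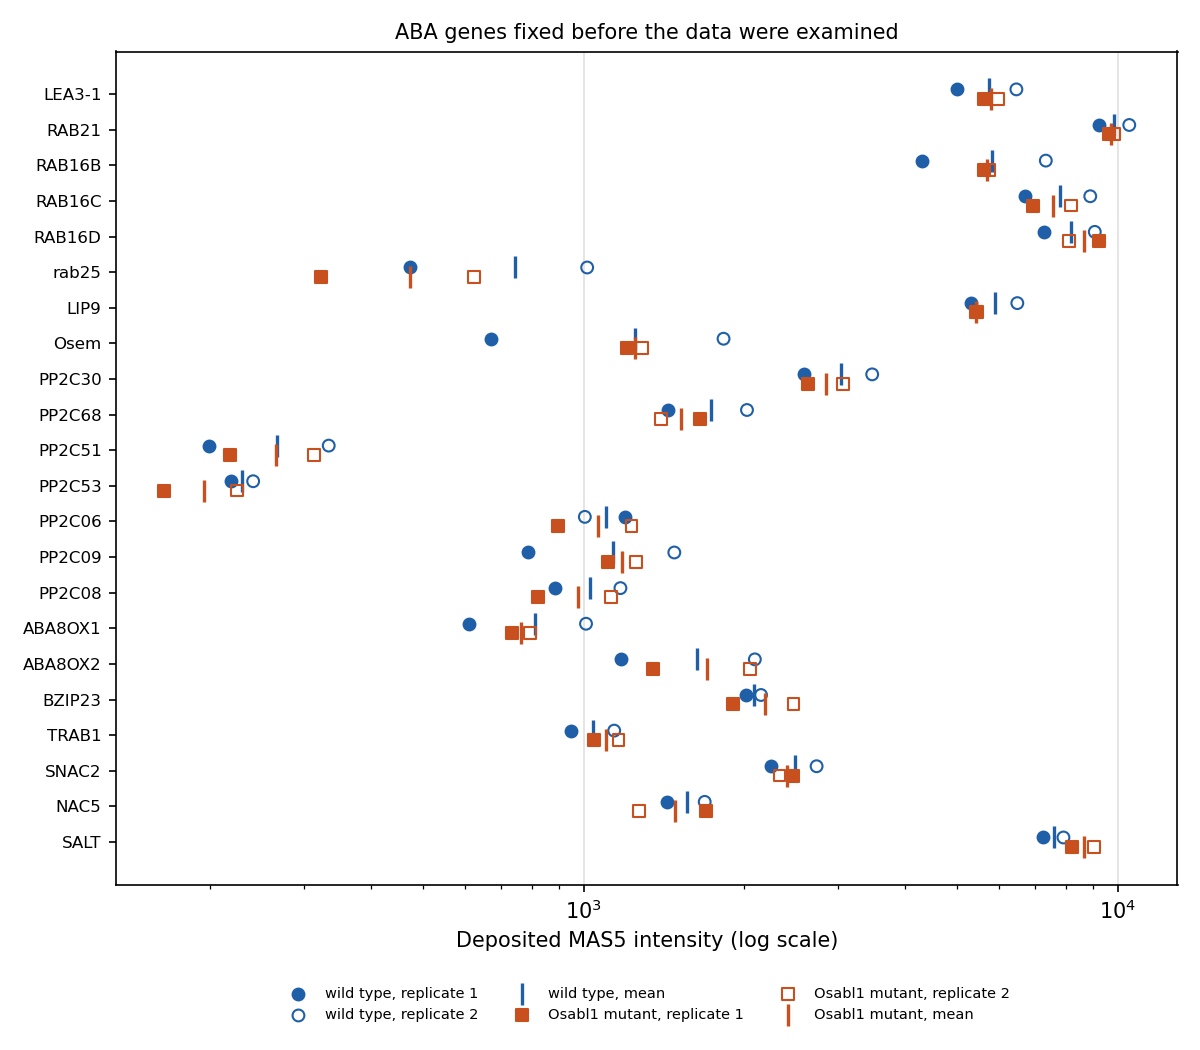
Deposited intensity (horizontal log axis) of the 22 ABA genes that could be matched; blue circles are wild-type arrays, orange squares mutant arrays, filled for replicate 1 and open for replicate 2, and vertical ticks mark the mean of 2 arrays. The genotypes overlap for all but SALT, whose mutant arrays (8224 and 9035) both lie above the wild-type arrays (7246 and 7910).

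Of 38 fixed gene lists, 13 had at least 5 tested genes. With camera and a preset correlation of 0.01, 6 lists were lower in the mutant and 0 higher (adjusted p under 0.05). The correlation between genes estimated for these 6 lists was between 0.475 and 0.885, far above the preset on which the small p-values rest. None of the 6 passed with camera at the estimated correlation (adjusted p = 0.73 for each) or with fry (adjusted p = 0.9483 for each). No single member passed over all genes. The list of diterpenoid phytoalexin synthesis, the pathways to rice defence compounds, had 5 of 5 tested genes lower. Their median log2 difference was -0.77 (camera, adjusted p = 7.573e-07). Adjusted over the list alone, 3 of them passed: CYP99A3 (870.4 ± 629.8 in the wild type and 334.0 ± 135.0 in the mutant, log2 difference -1.19), CYP99A2 (-0.97) and CYP76M6 (-0.77), each with an adjusted p of 0.03932 (limma). The genotypes overlapped for CYP99A3 (425.0 and 1316 in the wild type, 238.5 and 429.5 in the mutant). CYP76M6 was dim, at 25.5 in the wild type and 9.0 in the mutant. The list was called whichever array was left out, but its mean log2 difference of -0.74 moved with single arrays as deposited, to -1.08 without wild-type replicate 1, -0.40 without wild-type replicate 2, -0.48 without mutant replicate 1 and -1.001 without mutant replicate 2. The wider cytochrome P450 list, which shares members with it such as CYP99A2 and CYP99A3, had 18 of 26 genes lower (median -0.18, camera adjusted p = 4.638e-05). Its mean log2 difference of -0.29 was -0.008 without wild-type replicate 2 as deposited, and -0.15 on centred arrays without that array. In the wider list, AOS2 (LOC4332121), an allene oxide synthase of the jasmonate pathway, was at 284.8 and 80.9, a log2 difference of -1.58. AOS2 passed adjusted over the list alone (limma, adjusted p = 0.0145) but not over all genes (0.5119).

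The lists could only match gene names, and 2452 of the 17905 genes paired with a probe set carry a name beyond a LOC number. Counts of list members thus cover named genes, not whole families. The WRKY transcription factors, many of which act in defence, had 6 of 6 tested genes lower (median -0.67, camera adjusted p = 4.638e-05). Among them were WRKY76 (-0.75), WRKY24 (-0.71), WRKY62 (-0.69) and WRKY71 (-0.65), none of which passed alone. WRKY24 was dim, at 26.6 in the wild type and 9.4 in the mutant. The NAC factors had 7 of 7 lower (median -0.22, camera adjusted p = 0.005528), with NAC4 (LOC4327485) at -0.88 and ONAC045 at -0.85. The ERF and DREB factors had 4 of 5 lower (median -0.25, camera adjusted p = 0.03761), with DREB1B at -0.96 and DREB1A at -0.54. That call was also lost on centred arrays (adjusted p = 0.05887) and with quantile normalization (0.09392). The mean log2 difference of this list hardly moved, at -0.35 as deposited, -0.34 on centred arrays and -0.33 with quantile normalization. Its adjusted p ranged from 0.007388 to 0.9483 over its alternatives. The heat shock proteins had 16 of 23 lower (median -0.18, camera adjusted p = 0.0009583), with HSP16.9B at -0.84 and HSP101 at -0.61. On centred arrays, both mutant arrays lay below both wild-type arrays in 5 of the 6 lists, all but the heat shock proteins. A given order of 2 against 2 arrays arises by chance in 16.7% of cases. The lists were called on these same arrays, so this order is no further support. In the WRKY, NAC and heat shock lists the 2 wild-type arrays differed from each other by 0.60, 0.38 and 0.58, at least as much as the genotypes (-0.54, -0.34 and -0.25), with wild-type replicate 2 the highest of the 4 arrays. Without that array only diterpenoid phytoalexin synthesis was called. The adjusted p were then 0.1591 for WRKY, 0.2764 for NAC, 0.2764 for ERF and DREB and 0.6158 for the heat shock proteins, whose mean log2 difference turned from -0.25 to 0.19 as deposited. Without mutant replicate 1 the ERF and DREB factors (0.3221) and heat shock proteins (0.1344) were not called, and without mutant replicate 2 the NAC factors (0.132) were not, though their mean log2 difference of -0.37 stayed as large as with all arrays (-0.35; -0.23 on centred arrays without that array).

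The remaining lists were not called by camera. Their adjusted p was 0.07238 for MYB factors (8 of 10 lower), 0.08825 for jasmonate synthesis and TIFY (10 of 14 lower), 0.2057 for auxin response genes (4 of 8 lower) and 0.8722 for phosphate starvation (3 of 6 lower). Under other settings, MYB factors were called lower without wild-type replicate 1 on centred arrays (0.04835). Jasmonate synthesis and TIFY were called lower with quantile normalization (0.02904) and without mutant replicate 2 on centred arrays (0.03448). The phosphate starvation list had a median of 0.007, while camera, which compares a list with all other genes, gave the direction as lower. The ratio of 3' to 5' signal, which rises as RNA degrades, was between 10.8 and 14.8 for actin and between 2.16 and 3.18 for GAPDH over the 4 arrays. It was between 2.26 and 4.15 for cyclophilin and between 0.633 and 0.795 for ubiquitin, and wild type and mutant overlapped for each of the 4 transcripts. Wild-type replicate 2, the array on which the calls of 5 lists depended, had the highest ratio for actin (14.8) and cyclophilin (4.15), but not for GAPDH (2.47) or ubiquitin (0.707).

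**Figure D3:**
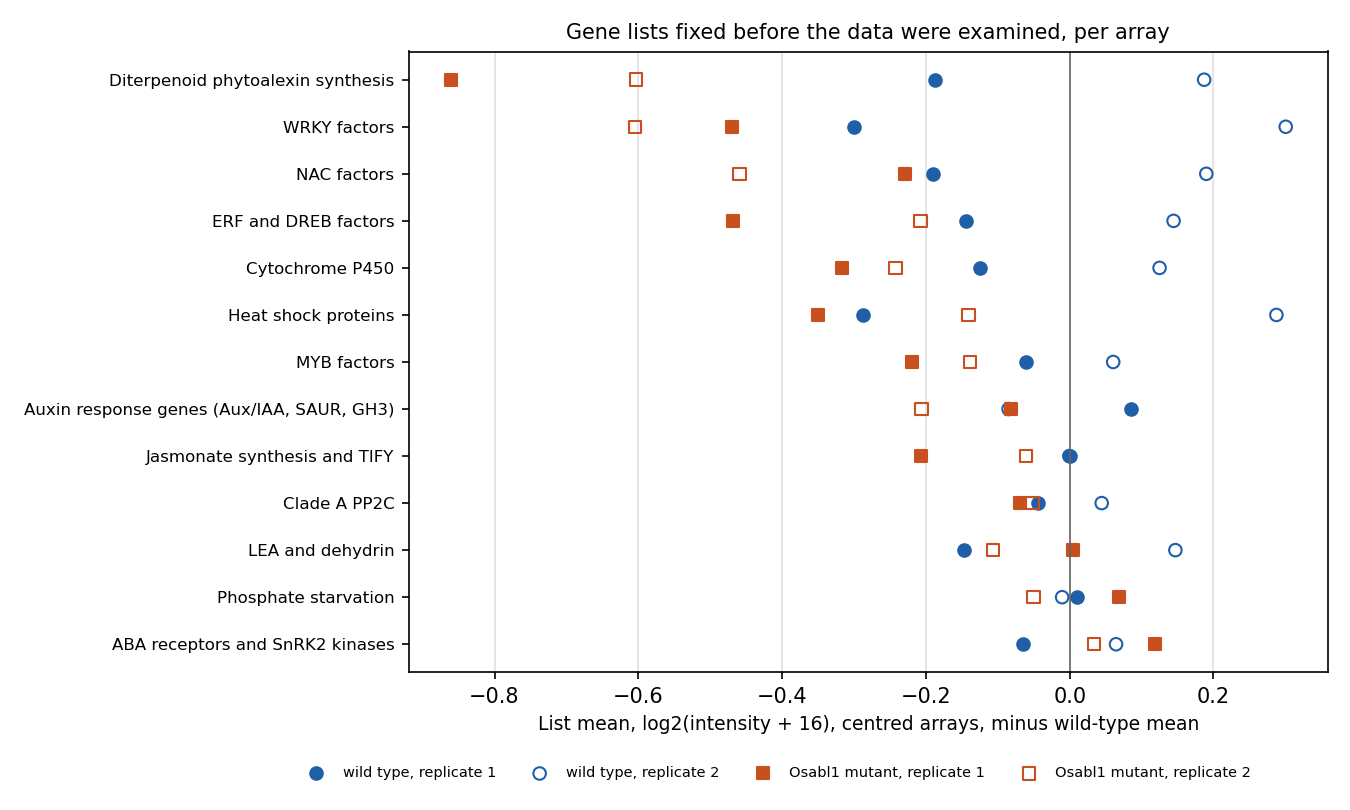
Mean of log2(intensity + 16) over the members of each of the 13 tested lists, on arrays centred on their median, minus the mean of the 2 wild-type arrays (horizontal axis, log2); blue circles are wild-type arrays, orange squares mutant arrays, filled for replicate 1 and open for replicate 2. The mutant arrays lie left of both wild-type arrays for diterpenoid phytoalexin synthesis and WRKY factors, and wild-type replicate 2 lies 0.60 above replicate 1 for WRKY factors.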

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

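The counts of called probe sets depended on the setting, and no called probe set changed sign. Against 7 higher and 0 lower, quantile normalization and centring gave 3 higher, no filter gave 1, the top 30% by mean gave 11 higher and 2 lower, and no moderation gave 0; the filter changes which probe sets share the adjustment, and the cause of the others was not tested. All 7 were among the calls with a pseudocount of 64, eBayes without trend and eBayes with trend and robust. Leaving out 1 array gave 33 to 58 higher and 6 to 260 lower as deposited. On centred arrays, a setting chosen after the data were seen, it gave at most 30 higher and 110 lower (both without wild-type replicate 1), and without wild-type replicate 2 it gave 17 higher and 1 lower, without mutant replicate 1 it gave 3 lower, and without mutant replicate 2 it gave 9 lower. These fits rest on fewer samples, and the lone array of a group is assumed to vary like the other group.

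Counts of 2-fold probe sets (20 higher, 9 lower) became 64 and 75 with a pseudocount of 1, and 11 and 0 with one of 64, since the pseudocount damps dim probe sets. They became 14 lower with centring or quantile normalization, and 67 to 169 higher and 30 to 339 lower with 1 array left out, where 2 pairs decide and not 4. Of the 2 reporter probe sets passing, 1 passed with no filter.

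The 6 fixed lists called lower became 3 with the top 30% by mean, where the other 3 (diterpenoid phytoalexin synthesis, WRKY, ERF and DREB) had under 5 tested genes and were not tested; they became 0 with camera at an estimated correlation, 0 with fry, and 1 without wild-type replicate 2, both as deposited and on centred arrays. Over the other arrays left out the count was at most 7. The heat shock list turned from -0.25 to 0.19 without wild-type replicate 2 (0.043 on centred arrays), with a range from -0.70 to 0.19 over the arrays left out; the cause was not tested. No fixed list was called higher with all arrays as deposited. Direction is read from camera, which sets a list against all other genes. The ABA panel had 0 members passing in every setting run for it. eBayes with robust was not run for lists, since camera has no such setting.

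The replicate numbers do not mark a shared batch in the labels, and the deviations of same-numbered arrays correlated at 0.16 across probe sets. With the replicate block there were 9 higher and 3 lower calls, and 9 and 3 on centred arrays with the block, and 2207 and 2230 probe sets at an unadjusted p under 0.05 against 1106 without it; as deposited, it also called the lists of MYB factors (adjusted p = 0.0346) and JAZ repressors (0.04663) lower. Among single genes and probe sets the text could name, 57 values crossed into the threshold and 16 out of it over the alternatives counted. None of these changed sign. The 16 leave out least squares without moderation, where every called probe set fell out of the threshold. They also leave out losses in the fits on centred arrays with an array left out. Direction was judged only where either fit made a call: of 2566 values called in neither fit, 80 changed sign. No OsABL1 value could be recomputed. Intensities under the pseudocount of 16, from 53.6% to 56.7% of probe sets per array, limit what can be said of dim genes.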

Other observations

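Chosen only after the results had been seen were the gene families, leaving out arrays on centred arrays, and the tests of the 2 patterns below other than that of the splits of the arrays for called lists. Gene families built from gene names added groups that the fixed lists lacked. With camera at a preset correlation, 5 of 34 tested families were higher in the mutant and 1 lower. None passed with camera at an estimated correlation (adjusted p = 0.9264) or with fry (smallest adjusted p 0.917). The estimated correlation was between 0.371 and 0.83 for the 5 families called higher and -0.058 for the 1 called lower. The cellulose synthases, which build the cell wall, had 9 of 9 genes higher (median log2 difference 0.36, camera adjusted p = 0.0008464), led by CESA7 (1.15) and CESA4 (0.79). CESA7 stood at 184.5 and 765.7 in the mutant, and without mutant replicate 2 the list was not called. Its mean log2 difference of 0.47 was then -0.02 as deposited and 0.12 on centred arrays. Expansins, which loosen walls, had 16 of 20 higher (median 0.24, camera adjusted p = 0.00359), with EXPA1 at 0.78. Aquaporins had 22 of 24 higher (median 0.16, camera adjusted p = 0.01217), with the dim PIP2-8 at 0.87 (17.8 in the wild type, 46.4 in the mutant). Neither family was called without mutant replicate 2. Without that array their mean log2 differences went from 0.27 to 0.02 and from 0.21 to -0.002 as deposited, and were 0.16 and 0.14 on centred arrays. On centred arrays the expansins were not called without wild-type replicate 1 (mean log2 difference 0.31) or mutant replicate 2. The aquaporins were not called there without wild-type replicate 2 (mean log2 difference 0.17) or mutant replicate 2. Genes of DNA replication (19 of 25 higher, camera adjusted p = 0.03924) and ribosomal proteins (21 of 23 higher, camera adjusted p = 0.03924) each had a mean log2 difference of 0.18. As deposited, neither was called without mutant replicate 2 (means 0.008 and 0.08) or without wild-type replicate 1 (-0.002 and -0.08). The ribosomal proteins were also not called without mutant replicate 1, where their mean was 0.28. On centred arrays DNA replication was not called without wild-type replicate 1, mutant replicate 1 or mutant replicate 2. Its mean log2 difference was then 0.16, 0.24 and 0.15. The ribosomal proteins were not called there without wild-type replicate 1 or mutant replicate 1, at mean log2 differences of 0.08 and 0.16. Other settings also ended these calls. The aquaporins were not called with quantile normalization (0.05392) or no filter (0.07342), and the ribosomal proteins not with quantile normalization (0.09477), eBayes without trend (0.06002) or the mean of all probe sets of a gene (0.08729). DNA replication was not called with a pseudocount of 1 (0.1206), the top 30% by mean (0.6612), eBayes without trend (0.05281) or the mean of all probe sets of a gene (0.06127). ABC transporters of the G class had 7 of 8 lower (median -0.32, adjusted p = 0.002857), with ABCG36 at 278.9 in the wild type and 93.0 in the mutant and ABCG37 at -0.69, and were not called without mutant replicate 2 (adjusted p = 0.1841) or wild-type replicate 1 (0.2153). Their mean log2 difference of -0.40 was then -0.37 and -0.47 as deposited, and -0.23 and -0.30 on centred arrays. Members of this family had been seen among the smallest p before the list was built. Its direction is therefore not independent evidence. The other 28 families were not called, among them bZIP factors (adjusted p = 0.9877), photosynthesis genes (0.4761), HAK transporters (0.1325), glutaredoxins and thioredoxins (0.081) and CASP-like proteins (0.3385). Jasmonate synthesis was not called either (0.2757), and its median of 0.05 and mean of -0.13 differ in sign. Of the 28, 10 were called under at least 1 alternative. Glutaredoxins and thioredoxins were called higher without wild-type replicate 2 (0.02426 as deposited, 0.04451 on centred arrays), and jasmonate synthesis lower with the top 30% by mean (0.03263). The JAZ repressors of jasmonate signalling (0.06715) were called lower with quantile normalization (0.01488), centring (0.04139), no filter (0.04847) and the top 30% by mean (0.04112). The Aux/IAA proteins (0.1) were called higher on centred arrays (0.04721) and with a pseudocount of 64 (0.04248), and the calmodulin-like proteins (0.05547) lower with a pseudocount of 64 (0.04248) and the top 30% by mean (0.03263), and without wild-type replicate 1 (0.002218) or mutant replicate 2 (0.009774). The other 5 were auxin response factors, heat stress factors, phosphate transporters, SWEET transporters and trehalose enzymes.

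Among members of these families, the iron transporter YSL15 stood at 312.7 in the wild type and 640.1 in the mutant (log2 difference 1.00), and the lipoxygenase gene LOX9 differed by -1.19; neither passed over all genes. Spike-ins added before labelling differed between replicates by -0.06 in the wild type and -0.23 in the mutant, where hybridisation spike-ins differed by 0.49 and 0.28 and the tested probe sets by 0.25 and 0.21 (replicate 2 minus replicate 1, median log2).

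A first pattern was the set of probe sets higher in the mutant. For the size of the 7 log2 differences, the values argue against array brightness. With quantile normalization their largest move toward 0 was -0.04017, against a standard error of 0.31. The lowest of the 7 was 2.21, while the median log2 difference of all tested probe sets was 0.01. Brightness was thus nearly balanced between the genotypes, and rescaling had little difference between them to remove. The small move with quantile normalization is therefore no separate evidence. The calls themselves did depend on the scaling. Those lost on centring (7 to 3) went with fewer prior degrees of freedom (12.28 to 6.39), not with smaller folds. A segment around OsABL1 that differs in the mutant line could place changed genes near it on chromosome 6. Of the 26 single-gene probe sets with an unadjusted p under 0.001 (limma), higher or lower, 11.54% lie on chromosome 6 against 7.93% of all tested. These are too few to decide (exact hypergeometric p = 0.3404, one-sided, upper 95% limit 30.1%). The share also covers the whole chromosome and includes lower probe sets, so nearness to OsABL1 was not tested. The 3 splits of 4 arrays are too few to exclude chance: 1 split, the real one, gave as many as 7 calls, and the highest other gave 0. At an unadjusted p under 0.05, however, the split by replicate number gave 4204 against 1106 for the genotypes. As deposited, the replicate 2 arrays were the brighter ones in both genotypes. On centred arrays the counts were 2039 (7.13%) against 1562 (5.46%), where 5% is expected if nothing differs. What remains along the replicate number was not tested. The loss of OsABL1 and other features of this single mutant line stay open, as no second allele is in the labels.

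A second pattern was the set of gene lists lower in the mutant. That 1 array stands apart is a candidate explanation: without wild-type replicate 2 the heat shock list kept -0.7441 of its mean difference as deposited, and 5 of the 6 lists kept at most 0.166 of theirs. Leaving out 1 array also unbalances brightness, and on centred arrays only the heat shock list did so (-0.1756), while the other 5 kept from 0.44 to 0.74. That list members vary together between root samples of 1 genotype is another candidate for 3 of the 6 lists. On centred arrays, their wild-type replicates differed at least as much as the genotypes, and in the mutant 0 lists showed this. With 2 arrays per genotype, this spread also sets what a list keeps without wild-type replicate 2. The 2 tests thus read the same difference and are not separate evidence. Of the 3 splits, too few for a test, 1 gave as many as 6 called lists and the highest other gave 4. The mutant genotype itself, the biological difference in the design, stays open, as untested.

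Of the ABA genes, the 15 with a mean intensity under 3000 had a median absolute log2 difference of 0.083, and the 7 brighter ones had 0.037. Compression of bright signals was not tested, and neither was any biological explanation.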
